A study of Mus musculus with 3 samples.

How the data were processed

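DRUG-seq2, a barcoded reverse transcription assay in which the wells of a plate are pooled and sequenced as 1 library, was applied to mouse embryonic fibroblasts (MEF) kept for 4 days in a medium called CFAE+8 with 1 compound of a commercial kinase inhibitor library per well, per the labels' protocols. The 3 deposited samples are 3 whole plates, and the barcode lists name the wells of each. The deposited table holds a whole-number count per gene and well, and the authors applied no scaling to it, as the values are whole numbers. Reads were aligned with STAR to mm10, per the submitters' processing notes. The STAR version, the counting tool, the annotation, the use of strand and any collapsing of molecular identifiers are not given in the sources used here. Gene positions were taken from GENCODE vM21 on mm10. The table had 20471 genes, of which 26 carried names that a spreadsheet had turned into dates. It held 0 ERCC spike-in genes, so the yield of a well was measured by its total count.

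The table had 274 columns, of which 258 were given to a plate by the barcode lists. The other 16 columns were not used: 6 had a name in no list (3 each of bC8FAE_BI and bC8FAE_MSC), and 10 belonged to 5 compounds that 2 plates listed under the same name. Another 4 columns (MCB_613, CC_115, Erdafitinib and MRT67307, each listed for 2 wells) repeated a column of the same name exactly and were counted as 1 well with it, which left 254 wells. Whether such a count comes from 1 well or both is not given in the sources used here. A total of 218 compound wells had at least 10% of the median total of their plate and entered the gene tests. A compound with more than 1 salt form on a plate entered as 1 compound, which gave 211 tests. No well was named as a vehicle control. Each compound was compared with all other wells of its plate in the screening medium, which on plate 3 included 5 wells named bC8FAE, taken as the screening medium without a compound from their name. A well that shared a response with many other compounds therefore differed less from its reference. Plate 3 also held wells named MEF, basal, bCFAE, bC6FAE[2], bC6FAE[10], bCLFAE and bCSFAE, with 3 to 4 wells each, and 2 wells named nocell. The letters and numbers in these medium names are not explained in the sources used here and are used as names only.

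Changed genes were tested with edgeR 4.0.16 (R 4.3.3): trimmed mean of M values (TMM) scaling, filterByExpr with a minimum count of 10, and the quasi-likelihood test with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. The spread of a compound's fit was estimated over all wells of its plate, since most compounds had 1 well. The media comparisons shared 1 fit of 30 wells and 6985 genes. Target classes, written from general knowledge of the compounds' main targets, were compared with the other screening wells of the same plates with a plate term. The table held 40 classes, and those with at least 3 compounds were tested, together with the 2 CDK8/19 inhibitors. Log2 fold changes are given with their standard errors (SE). Adjusted p values in the text come from edgeR unless another tool is named. For a gene at 0 counts in a group, the bound printed as "at least" sets that group at 3 counts over its total, and for 1 to 3 counts the ratio has a 95% interval. Shares have 95% Wilson intervals. Floors and intervals cover counting error only.

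A total of 26 gene lists were fixed before the data were examined, as were the tests, the target classes and the rule for named genes. The lists were fibroblast and mesenchymal identity, epithelial, extraembryonic endoderm, pluripotency, inflammatory and NF-kappaB response, interferon response, G2/M phase, DNA replication and S phase, p53 targets, ERK pathway targets, amino acid response and ATF4 targets, FOXO targets and PI3K feedback, cholesterol synthesis, smooth muscle and SRF targets, YAP targets, TGF-beta response, Wnt targets, heat shock and protein folding, unfolded protein response, autophagy and lysosome, mitochondrially encoded, macrophage, endothelial, skeletal muscle, neural and adipocyte. Lists were tested per comparison and per compound with camera (limma 3.58.1) on voom values, with the correlation between genes preset at 0.01. Every such result was repeated with an estimated correlation, and fry gave a test of whether the genes move on balance in 1 direction. Class scores, the mean over a list of log2(CPM + 1) minus the mean of the reference wells (counts scaled by the library total to CPM), were compared with a two-sided permutation test of 100000 resamples within plates. The smallest p this test can give is 1e-05.

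The named genes of a comparison were the 10 with the largest rise and the 10 with the largest fall among called genes with a mean of at least 10 CPM that changed the same way in every well. To these were added up to 4 called members of each list, which did not have to change the same way in every well. They are given for the 6 classes with the most called genes and for CDK8/19, for the 10 compounds with the most called genes, for compounds at the ends of a list, and for 4 media comparisons. Gene models without a symbol, pseudogenes and ribosomal RNA were left out. The media comparisons were written after the well names were seen and before the counts were examined. In addition, 47 compound aliases were added after the well names were seen.

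Profiles of wells were compared with Pearson's r across genes of log2 fold changes, with a one-sided permutation test of the well names. The alternatives were DESeq2 1.42.0 as the test, DESeq2 size factors in place of TMM, other low-count filters, other well minimums (none, and 25% of the plate median), another reference on plate 3, other pseudocounts, list medians, thinned wells and the leaving out of single wells or compounds. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The fits were tested on simulated data with 200 changed genes and a dispersion of 0.05. For 1 well against plate 2, 13.4%, 83.6% and 93.9% of genes changed by 1, 2 and 3 on the log2 scale were recovered. Of the calls, 3.79% were false. Real reference wells held different compounds, so real rates are unknown. For 5 against 4 wells of plate 3, 57.1% were recovered at a change of 1 and 100% at 2. The p values measure only the spread between wells, as the labels name no separate MEF preparations. Since the use of strand is not given, 87 of the 602 named genes cannot be told from a neighbour whose exons they overlap.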

Results

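Gene expression was measured by DRUG-seq2 in wells of mouse embryonic fibroblasts (MEF) on 3 plates, most of which had received 1 compound of a kinase inhibitor library for 4 days. Plate 1 held 87 tested compounds, plate 2 held 84 and plate 3 held 40. Plate 3 also held wells named for a medium and not for a compound: 4 of MEF, 3 of basal, 3 of bCFAE, 5 of bC8FAE, 3 of bC6FAE[2], 4 of bC6FAE[10], 4 of bCLFAE and 4 of bCSFAE. What these media held is not given in the sources used here. The median total count per screening well was 318166 on plate 1 (range 5154 to 591025), 606767 on plate 2 (3196 to 1206219) and 427868 on plate 3 (3528 to 703918). The wells named for a medium had totals of 119295 to 726228, with a median of 448881. The 2 lowest of them were bC8FAE 4 with 119295 and MEF 3 with 138747.

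The basal and MEF wells were compared to ask how these media differed. Among the genes that rose in basal medium were Fabp4, a fatty acid carrier, by a log2 fold change of 2.63 ± 0.45 (SE; 3 against 4 wells), Angptl4, an inhibitor of lipoprotein lipase, by 1.98 ± 0.18, Cpt1a, which imports fatty acids into mitochondria, by 1.31 ± 0.19, and the thioesterase Acot2 by 1.18 ± 0.29. The chemokine Ccl9 rose by 2.54 ± 0.32, angiotensinogen (Agt) by 2.32 ± 0.52, the chemoattractant Rarres2 by 1.73 ± 0.17 and the glucose-responsive Txnip by 0.97 ± 0.21. Of 4 adipocyte genes, 1 rose, and the list was not called (camera adjusted p = 0.082, and 0.187 with an estimated correlation). The water channels Aqp5 (-2.95 ± 0.62) and Aqp1 (-1.30 ± 0.32) fell, as did S100a4 (-1.40 ± 0.17), dermatopontin (Dpt, -1.16 ± 0.24), the interleukin receptor Il1rl1 (-1.15 ± 0.22), decorin (Dcn, -0.87 ± 0.20), Id1 (-0.87 ± 0.16) and Timp3 (-0.86 ± 0.17). The chemokine Ccl8 had 0 counts in basal wells and was at least 6.20-fold lower. Some of these calls were lost when 1 well was left out. Acot2 was not called without basal 1 (1.03), basal 3 (1.10) or MEF 4 (0.99), Agt without basal 2 (2.03), basal 3 (2.35), MEF 1 (1.97) or MEF 4 (1.957), and Txnip without basal 1 (0.92), basal 2 (0.86) or MEF 4 (0.82). Aqp1 was not called without basal 2 (-1.03), basal 3 (-1.28), MEF 2 (-1.02) or MEF 3 (-1.196), and Dcn without basal 1 (-0.79), basal 3 (-0.79) or MEF 3 (-0.47). Aqp5 was not called without MEF 4 (-2.33), Dpt without basal 2 (-0.92), Il1rl1 without basal 3 (-0.96), Timp3 without basal 1 (-0.76) and Ccl8 was not called when basal 1, 2 or 3 was left out. Of 25 measured fibroblast genes, 2 fell and 0 rose in edgeR's test, and 4 fell when adjusted over the list alone. The list as a whole was lower (camera adjusted p = 0.00119), with adjusted p = 0.0603 with an estimated correlation (0.0492 without the low wells MEF 3 and bC8FAE 4). Cholesterol synthesis (21 measured, 0 called; also 0 when adjusted over the list alone) and autophagy and lysosome genes (18 measured, 0 called; 2 fell when adjusted over the list alone) were lower as lists in camera, and both held with an estimated correlation (adjusted p = 0.0343 and 0.0319). The p53 targets and the TGF-beta response passed at the preset correlation and were lost at an estimated one (adjusted p = 0.17 and 0.15 with an estimated correlation). Without the low wells they did not pass at the preset one either (adjusted p = 0.0698 and 0.159). Of 17 inflammatory genes, 1 rose and 1 fell (1 and 3 when adjusted over the list alone), and the list was not called (camera adjusted p = 0.129, and 0.584 with an estimated correlation). Without MEF 3 and bC8FAE 4 it was higher in basal medium, with adjusted p = 6.3e-07, or 0.00043 with an estimated correlation. The call for this list therefore depended on the low wells. In all, edgeR called 48 genes, 26 higher and 22 lower, and 664 genes had an unadjusted p under 0.05. The count was 25 without basal 1, 31 without basal 3, 30 without MEF 4, and 76 without both of the low wells, MEF 3 and bC8FAE 4.

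The bCFAE and basal wells, 3 of each, were compared to ask how these media differed. Some genes had 0 counts in bCFAE: Lcn2 was at least 97.9-fold lower, Sfrp4 at least 66.1-fold, C1ra at least 62.8-fold, the metalloreductase Steap4 at least 58.2-fold, Calml4 at least 40.3-fold, Lbp and Ptn at least 38.4-fold and the complement gene C3 at least 25.1-fold. These bounds give no order among the genes. The ratio for Saa3 was 0.00123 (95% interval 3.1e-05 to 0.00687). The complement inhibitor Serping1 fell by 7.84 ± 0.36 on the log2 scale, and the neutrophil chemokine Cxcl5 fell by 7.14 ± 1.04. Of 17 measured inflammatory genes, 13 fell and 0 rose (14 fell when adjusted over the list alone; camera adjusted p = 8.9e-05, adjusted p = 0.17 with an estimated correlation). In the fit without MEF 3 and bC8FAE 4 the list held with an estimated correlation (adjusted p = 0.00056). Matrix genes fell as well: Lox, which cross-links collagen (-5.18 ± 0.25), Dcn (-4.31 ± 0.34), Lum (-3.37 ± 0.49), Col3a1 (-2.93 ± 0.22) and Postn (-2.85 ± 0.35). Of 25 fibroblast genes, 17 fell and 3 rose (18 and 3 when adjusted over the list alone), and the list held with an estimated correlation (camera adjusted p = 0.0055). The adipocyte genes Fabp4 (ratio 0.00764, 95% interval 0.000190 to 0.0441) and Lpl (-5.63 ± 0.43) fell, and so did 3 of 4 adipocyte list members (4 when adjusted over the list alone), which held with an estimated correlation (adjusted p = 0.034). In the fit without MEF 3 and bC8FAE 4 it held with the preset correlation only (adjusted p = 0.00475, and 0.088 with an estimated correlation).

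Wnt and ERK target genes rose in bCFAE. Tnfrsf19, Axin2 and Lef1 had 0 counts in basal wells and were at least 19.2-fold, 5.38-fold and 3.53-fold higher. Of 11 Wnt targets, 7 rose and 0 fell (also 7 when adjusted over the list alone; camera adjusted p = 0.0015, adjusted p = 0.060 with an estimated correlation). The ERK-driven transcription factors Etv4 (3.59 ± 0.28) and Etv5 (2.34 ± 0.42) and the cyclin Ccnd1 (2.43 ± 0.16) rose. Of 12 ERK targets, 9 rose and 1 fell (the same counts when adjusted over the list alone), and the list held with an estimated correlation (adjusted p = 0.0028). Neuronal genes rose: the neurofilaments Nefl (4.01 ± 0.48) and Nefm (3.08 ± 0.41), whose exons overlap each other in the annotation, Gap43 (2.28 ± 0.24), and Nptx1, Tmem179 and Syn1, which had 0 counts in basal wells and were at least 24.7-fold, 25.4-fold and 9.24-fold higher. Of 6 neural genes, 4 rose (4 when adjusted over the list alone; adjusted p = 0.11 with an estimated correlation). The retinol transporter Stra6 rose by 7.12 ± 0.29, the chaperone Cryab by 2.83 ± 0.22, Hspa8 by 2.72 ± 0.59, Mdm2 by 1.88 ± 0.24 and the replication genes Mcm2 and E2f1 by 1.32 ± 0.28 and 1.17 ± 0.21. Of 21 S phase genes, 9 rose (9 when adjusted over the list alone; adjusted p = 0.054 with an estimated correlation), and of 13 heat shock genes, 7 rose (7 when adjusted over the list alone; adjusted p = 0.017 with an estimated correlation). All 4 measured epithelial genes rose (4 when adjusted over the list alone; adjusted p = 0.12 with an estimated correlation), Krt18 by 1.63 ± 0.48. Cholesterol synthesis fell, with Fdft1 at -1.95 ± 0.23 and Mvd at -1.38 ± 0.20 among 10 of 21 members (12 when adjusted over the list alone; adjusted p = 0.11 with an estimated correlation). Of 16 unfolded protein response genes, 7 fell (9 when adjusted over the list alone; adjusted p = 0.12 with an estimated correlation). The fit called 2411 genes, 1141 higher and 1270 lower, the most of any media comparison run.

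The bC8FAE and MEF wells, 5 and 4, were compared to ask how the wells taken as the screening medium without a compound differed from those named MEF. Smooth muscle genes fell: Acta2 (chromosome 19, 34241090 to 34255590 on mm10) was at 129 ± 25.3 CPM (SD, n = 5) against 2249 ± 609 CPM (n = 4), a log2 fold change of -4.18 ± 0.16, and Actg2 (-5.75 ± 0.30) and Tagln (-3.18 ± 0.21) fell with it. Exons of Tagln overlap those of Pcsk7. Of 18 measured smooth muscle genes, 13 fell and 1 rose (the same when adjusted over the list alone), which held with an estimated correlation (camera adjusted p = 0.0083). Lcn2 had 0 counts in bC8FAE and was at least 136-fold lower, C3 at least 42.7-fold and the pentraxin Ptx3 at least 36.3-fold, and the ratio for Saa3 (chromosome 7, 46711998 to 46715700) was 0.00109 (95% interval 0.000224 to 0.00318). These folds rested on the low MEF 3 well, with 11865 CPM of Saa3 against 7.82 to 43.6 CPM in the other 3. Without MEF 3 the ratio for Saa3 was 0.0529 (0.0103 to 0.169), and the bounds were 15.3-fold for Lcn2 and 18.3-fold for C3. Without MEF 1 they were 0.000700 (0.000144 to 0.00205), 206-fold and 65.4-fold. Of 17 inflammatory genes, 12 fell and 1 rose (12 and 2 when adjusted over the list alone; camera adjusted p = 0.0008, adjusted p = 0.24 with an estimated correlation). The list stood at a mean log2(CPM + 1) of 8.61 in the low MEF 3 well and at 6.14 to 6.31 in the other 3 MEF wells. Without MEF 3 and bC8FAE 4 it held with an estimated correlation (adjusted p = 0.0053). Serping1 (-7.35 ± 0.28), Lox (-6.32 ± 0.27), Lpl (-4.93 ± 0.42), Postn (-3.37 ± 0.34), Col5a2 (-2.76 ± 0.18) and Lum (-2.55 ± 0.30) fell, and Dcn (chromosome 10, 97479609 to 97518143) fell by 3.70 ± 0.24. Of 25 fibroblast genes, 15 fell and 7 rose (the same when adjusted over the list alone), which held with an estimated correlation (adjusted p = 0.017).

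All 11 measured Wnt targets rose in bC8FAE against MEF (11 when adjusted over the list alone; adjusted p = 0.0023 with an estimated correlation). Nkd1, a feedback inhibitor of Wnt signalling (chromosome 8, 88521354 to 88594884), rose by 5.04 ± 0.29, and the ratios of MEF to bC8FAE were 0.0281 for Axin2 (95% interval 0.000699 to 0.163), 0.0325 for Tnfrsf19 (0.00662 to 0.0967) and 0.0356 for Tcf7 (0.00424 to 0.132). The ERK targets Etv4 (2.90 ± 0.24; chromosome 11, 101769742 to 101785371), Etv5 (2.68 ± 0.34) and Ccnd1 (2.56 ± 0.13) rose with 8 of 12 list members (8 rose and 1 fell when adjusted over the list alone; adjusted p = 0.0013 with an estimated correlation). The synaptic protein gene Nrgn rose by 6.58 ± 0.28, the replication licensing gene Cdt1 by 2.01 ± 0.33 and Id1 by 1.33 ± 0.12. Of 21 S phase genes, 6 rose (6 when adjusted over the list alone; adjusted p = 0.032 with an estimated correlation). Without MEF 3 and bC8FAE 4 the S phase list had adjusted p = 0.0145 with the preset and 0.05002 with an estimated correlation. Sterol genes fell, with 14 of 21 list members lower (15 when adjusted over the list alone; adjusted p = 0.0083 with an estimated correlation). The fit called 2241 genes, 1061 higher and 1180 lower.

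The bC8FAE and bCFAE wells, 5 and 3, were compared to ask how these media differed. Acta2 was at 129 ± 25.3 CPM in bC8FAE and 1348 ± 104 CPM in bCFAE (SD), a log2 fold change of -3.43 ± 0.16. The contractile genes Actg2 (-3.06 ± 0.43), Tagln (-2.89 ± 0.21) and Cnn1 (-2.49 ± 0.33) and the LIM protein gene Fhl1 (-3.23 ± 0.25) fell too, and the bC8FAE to bCFAE ratio for Lmod1 was 0.0477 (95% interval 0.00115 to 0.297). Of 18 smooth muscle genes, 13 fell and 0 rose (15 fell when adjusted over the list alone), and camera's adjusted p was 4.9e-25, or 0.000115 with an estimated correlation. The protease Prss23 fell by 4.14 ± 0.37, and so did the TGF-beta-induced gene Pmepa1 (-1.59 ± 0.12), the keratins Krt19 (-2.17 ± 0.38) and Krt18 (-1.65 ± 0.39), Timp3 (-1.58 ± 0.16) and the receptor kinase Axl (-1.35 ± 0.14). Tgfbi, also a TGF-beta-induced gene, rose by 1.52 ± 0.17. Of 13 TGF-beta response genes, 4 rose and 4 fell (5 and 5 when adjusted over the list alone), and the list was not called by camera.

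Wnt feedback genes rose further in bC8FAE than in bCFAE: Wif1 by 2.91 ± 0.55, Notum by 2.72 ± 0.30 and Nkd1 by 1.57 ± 0.17. Of 11 Wnt targets, 6 rose and 0 fell (9 rose when adjusted over the list alone), which held with an estimated correlation (camera adjusted p = 0.0021). Aqp1 rose by 3.55 ± 0.24, the interferon-induced Ifitm1 by 2.93 ± 0.36, the homeobox gene Msx1 by 2.92 ± 0.22, Bmp4 by 1.83 ± 0.31, and the bCFAE to bC8FAE ratio for the basement membrane gene Frem1 was 0.0275 (95% interval 0.00558 to 0.0824). Fibroblast matrix genes were partly higher: Lum by 1.90 ± 0.54, S100a4 by 1.49 ± 0.19, Dcn by 1.48 ± 0.45 and Col6a1 by 1.33 ± 0.13. Dcn was not called without bC8FAE 1 (1.44), bC8FAE 5 (1.31), bCFAE 1 (1.31) or bCFAE 2 (1.49), and Lum without bC8FAE 5 (1.64), bCFAE 1 (1.86) or bCFAE 2 (1.67). Of 25 fibroblast genes, 10 rose and 2 fell (11 and 3 when adjusted over the list alone; adjusted p = 0.067 with an estimated correlation). Of 13 heat shock genes, 4 fell (4 when adjusted over the list alone; adjusted p = 0.048 with an estimated correlation). Without MEF 3 and bC8FAE 4 that list had adjusted p = 0.0103 with the preset and 0.05002 with an estimated correlation. Of 6 mitochondrially encoded genes, 3 rose, mt-Nd1 by 0.64 ± 0.16 (3 when adjusted over the list alone; adjusted p = 0.17 with an estimated correlation). The low well bC8FAE 4 stood apart on this list, with a mean log2(CPM + 1) of 10.33 against 9.33 to 9.61 in the other bC8FAE wells. The other 2 of these genes, mt-Cytb and mt-Nd4, were not called without bC8FAE 4 (0.26 and 0.28), bC8FAE 5 (0.44 and 0.49), bCFAE 1 (0.47 and 0.51), bCFAE 2 (0.47 and 0.55) or bCFAE 3 (0.42 and 0.43). Without bC8FAE 4 and MEF 3, all 3 were called (mt-Nd1 0.54, mt-Cytb 0.26, mt-Nd4 0.28), and the list had adjusted p = 0.0607 with an estimated correlation. The fit called 774 genes, 390 higher and 384 lower, of which 302 changed at least 2-fold, and 489 genes without bCFAE 1.

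**Figure D1:**
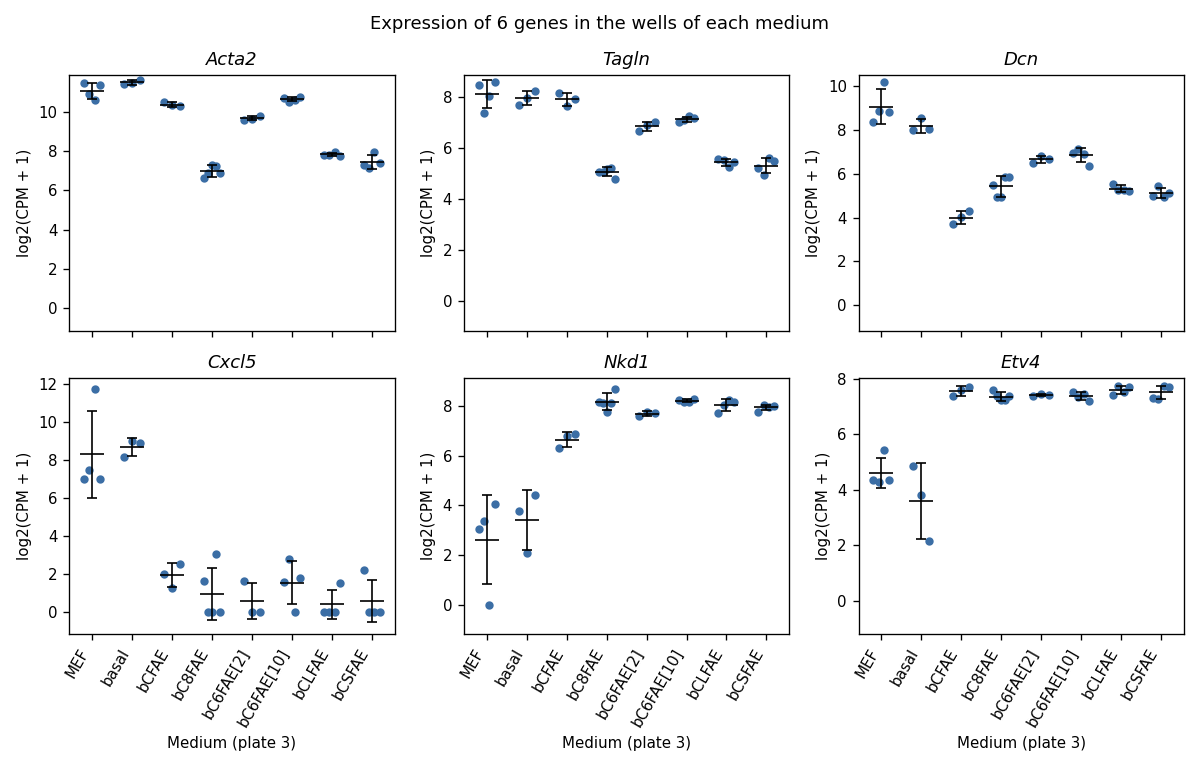
Expression of Acta2, Tagln, Dcn, Cxcl5, Nkd1 and Etv4 as log2(CPM + 1) in each well of plate 3 named for a medium, by medium, with 1 point per well and bars for the mean ± SD. Acta2 had a mean of 1348 CPM in bCFAE and of 129 CPM in bC8FAE.

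The other media were compared with the same 3 bCFAE wells to ask which of these changes they share, so they are not independent of the comparison above. Acta2 was lower in bCSFAE (-2.93 ± 0.16), bCLFAE (-2.56 ± 0.15) and bC6FAE[2] (-0.70 ± 0.15), and Tagln in bCSFAE (-2.63 ± 0.19), bCLFAE (-2.47 ± 0.19), bC6FAE[2] (-1.07 ± 0.18) and bC6FAE[10] (-0.80 ± 0.16). In bC6FAE[10], Acta2 was not called (0.27 ± 0.14; edgeR adjusted p = 0.231) and Actg2 was higher, by 0.98 ± 0.24. Of 18 smooth muscle genes, 13 fell in bCSFAE and 14 in bCLFAE (16 and 15 when adjusted over the list alone), both with an estimated-correlation adjusted p of 7.1e-05. In bC6FAE[2], 6 fell (9 when adjusted over the list alone; adjusted p = 0.061 with an estimated correlation, and 0.0386 in the fit without MEF 3 and bC8FAE 4). Acta2 was higher in bC6FAE[10] than in bC6FAE[2], by 0.97 ± 0.15 (edgeR adjusted p = 4.6e-05), as was Fhl1 by 0.92 ± 0.20 and Msx1 by 0.84 ± 0.17. Aqp1 rose by 3.57 ± 0.26 in bC6FAE[2], 3.91 ± 0.24 in bC6FAE[10], 2.52 ± 0.26 in bCLFAE and 2.94 ± 0.25 in bCSFAE, and Notum by 2.36 ± 0.35, 3.17 ± 0.29, 2.49 ± 0.31 and 2.28 ± 0.31. Of 11 Wnt targets, 7, 8, 6 and 5 rose in these 4 media (7, 8, 8 and 6 when adjusted over the list alone), and the list held in all 4 with an estimated correlation (highest adjusted p = 0.0071). Dcn rose by 2.73 ± 0.41 in bC6FAE[2] and 2.95 ± 0.37 in bC6FAE[10]. Of 25 fibroblast genes, 12 and 14 rose in these (13 and 16 when adjusted over the list alone; adjusted p = 0.0012 and 0.00097 with an estimated correlation), 7 in bCLFAE and 6 in bCSFAE (10 and 9 when adjusted over the list alone; adjusted p = 0.12 and 0.14 with an estimated correlation). In bC6FAE[10], 5 of 22 p53 targets rose (7 when adjusted over the list alone; adjusted p = 0.14 with an estimated correlation). The mitochondrially encoded list was higher in bC6FAE[2] and bC6FAE[10] with the preset correlation (adjusted p = 0.00876 and 0.0115; 0 and 2 of 6 genes rose, 3 in each when adjusted over the list alone), though not with an estimated one (adjusted p = 0.154 and 0.168). Without MEF 3 and bC8FAE 4 it held in both with an estimated correlation (adjusted p = 0.00986 in each), and was called in bCSFAE as well (adjusted p = 0.0365). The mitochondrial share of counts was 0.698% to 0.825% in bCFAE wells and 0.874% to 1.02% in the wells of these 4 media. Called genes numbered 599 in bC6FAE[2] (351 higher), 953 in bC6FAE[10] (530 higher), 454 in bCLFAE (224 higher), 426 in bCSFAE (222 higher), and 29 for bC6FAE[10] against bC6FAE[2] (19 higher). Without bCFAE 1 the counts were 276 in bCLFAE and 279 in bCSFAE. Without bC6FAE[2] 1 the count in bC6FAE[2] was 368. For bC6FAE[10] against bC6FAE[2] it was 8 without either bC6FAE[2] 1 or 2, and 18 without either bC6FAE[10] 3 or 4.

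The compounds were screened to ask which kinase inhibitors change the expression state of MEF in the screening medium. Each was compared with all other screening wells of its plate, and most had 1 well, so the difference of a single compound has no replicate check. Compounds carry their names from the barcode lists. Of 211 compounds, 161 had 0 genes called by edgeR, 15 had at least 100 and 4 had at least 1000. The 5 bC8FAE wells, tested the same way, had 0 to 5 called genes, and 7 of the 40 compounds of that plate exceeded this. Plates 1 and 2 had no such wells. The compounds with the most called genes were NT157 (2656), LDC4297 (1630), Erdafitinib (1101), Trametinib (1002), BEZ235 (957), FIIN_2 (925), LY3009120 (262 higher and 129 lower), GDC_0623 (353), MCB_613 (350) and PF_04979064 (348). Some counts depended on the method: GDC_0623 had 189 by DESeq2, and MCB_613 and PF_04979064 had 181 and 220 without a low-count filter. Against the bC8FAE wells alone, LY3009120 had 589. Plate 3 then had 7 compounds with at least 100, not 3, and 16 with any, not 7.

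**Figure D2:**
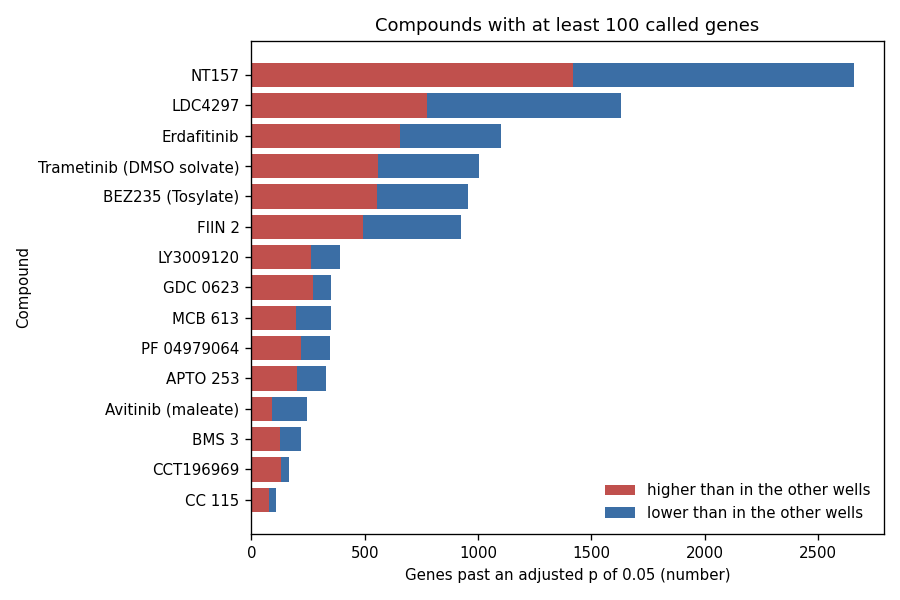
Number of genes called by edgeR at an adjusted p under 0.05 for the 15 compounds with at least 100 called genes, as stacked bars of higher and lower genes. NT157 had 1420 higher and 1236 lower genes.

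NT157, described as an inhibitor of insulin receptor substrate and STAT3 signalling, raised macrophage and lysosomal genes in its well on plate 2. Mcpt1, a mast cell protease (chromosome 14, 56017971 to 56020384), rose by 7.65 ± 0.43, the cathepsin Ctss by 6.44 ± 0.54, the metallothionein Mt3 by 6.33 ± 0.35, the macrophage elastase Mmp12 by 5.97 ± 0.59, Afp by 5.96 ± 0.55, the scavenger receptor Cd36 by 4.87 ± 0.65 and the lysozyme Lyz2 by 3.75 ± 0.41. Of 7 macrophage genes, 6 rose (6 when adjusted over the list alone), and camera's call held with an estimated correlation (adjusted p = 0.015). Also higher were the small heat shock protein gene Hspb1 by 3.70 ± 0.31, Hspa1b by 3.48 ± 0.53, the autophagy receptor Sqstm1 by 3.10 ± 0.29 and the chaperone Dnajb9 by 3.10 ± 0.31. Of 16 unfolded protein response genes, 10 rose (10 when adjusted over the list alone; adjusted p = 0.0059 with an estimated correlation), and of 22 autophagy and lysosome genes, 17 rose (17 rose and 1 fell when adjusted over the list alone; adjusted p = 0.89 with an estimated correlation). Thy1 (-4.72 ± 0.87), Col6a2 (-4.26 ± 0.67), Col6a1 (-3.84 ± 0.59) and Nkd1 (-3.30 ± 0.59) fell. Mitotic genes fell: Fam64a, Ccnb1, Prc1 and Mki67 had 0 counts and were at least 10.9-fold, 6.17-fold, 3.65-fold and 2.31-fold lower. Of 27 G2/M genes, 22 fell (24 when adjusted over the list alone; adjusted p = 1 with an estimated correlation). The mitochondrial share of the well was 1.91% of counts (95% Wilson interval 1.87% to 1.95%), above all but 2 of the 86 other compound wells of the plate (median 0.982%). DESeq2's size factors raised all folds of this well by a median of 0.104 on the log2 scale and gave 1594 higher and 1050 lower genes.

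LDC4297, a CDK7 inhibitor, lowered cell cycle and matrix genes on plate 3. Plk1 (-3.87 ± 0.71), Tk1 (-2.97 ± 0.63), Col6a2 (-3.80 ± 0.68), Tgfbi (-3.71 ± 0.60) and Col3a1 (-3.62 ± 1.02) fell, and Lrrn1, Ccnb2, Wif1 and Pola1 had 0 counts and were at least 17.5-fold, 9.82-fold, 5.89-fold and 4.37-fold lower. The ratio to the plate was 0.00858 for Nrgn (95% interval 0.00104 to 0.0310) and 0.0187 for Notum (0.000474 to 0.104). Of 24 S phase genes, 18 fell (22 when adjusted over the list alone), of 24 G2/M genes, 19 fell (22), of 26 fibroblast genes, 12 fell (12), and of 13 Wnt targets, 10 fell (12). None of these lists held with an estimated correlation (adjusted p = 0.61, 1, 0.49 and 1 with an estimated correlation). Among the higher genes were Fgl2 by 5.14 ± 0.66, Prss23 by 4.55 ± 0.78, Lmod1 by 3.98 ± 0.80, Tagln by 2.79 ± 0.64 and the YAP target Amotl2 by 2.82 ± 0.66. Of 18 smooth muscle genes, 6 rose (7 when adjusted over the list alone; adjusted p = 1 with an estimated correlation), and of 10 YAP targets, 4 rose (4; adjusted p = 0.83 with an estimated correlation). The mitochondrial share of the well was 1.89% of counts (95% Wilson interval 1.86% to 1.93%), the highest of the plate's compound wells (median of the other 40, 1.08%). Its 10 most counted genes held 5.19% of counts, the lowest share of these wells (median of the others 10.5%).

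Erdafitinib and FIIN_2, FGFR inhibitors on plate 2, lowered ERK targets. Under Erdafitinib, Sbspon rose by 5.59 ± 0.63, the chemokines Cxcl14 and Cxcl12 by 4.94 ± 0.73 and 4.90 ± 0.63, the proteoglycan gene Ogn by 4.80 ± 0.76, Col1a1 (chromosome 11, 94936224 to 94953042) by 3.98 ± 0.49, Col3a1 by 3.75 ± 0.41 and Lox by 3.74 ± 0.71. Etv4 (-3.47 ± 0.63), Etv5 (-3.04 ± 0.58) and Spp1 (-5.78 ± 1.60) fell, the ratio for Fosl1 was 0.0356 (95% interval 0.00734 to 0.104), and Spry4, an inhibitor of FGF signalling, had 0 counts and was at least 2.25-fold lower. Of 17 ERK targets, 9 fell (12 when adjusted over the list alone), and of 25 S phase genes, 10 fell (17). Of 26 fibroblast genes, 12 rose and 1 fell (14 and 4). These 3 lists had adjusted p = 0.61, 1 and 0.86 with an estimated correlation. The 10 most counted genes of the Erdafitinib well held 7.22% of counts, with 2 of 86 other compound wells lower (median 11.5%). Under FIIN_2, the hormone gene Sst rose by 6.91 ± 0.72, Saa3 by 5.66 ± 0.72, Igfbp2 by 5.26 ± 0.74, Ogn by 5.03 ± 0.83, Col1a1 by 3.58 ± 0.59 and the interferon-induced Gbp2 by 3.77 ± 0.97. Etv4 (-2.92 ± 0.69), Ccnd1 (-2.80 ± 0.47) and Etv5 (-2.76 ± 0.68) fell, and Agtr2 had 0 counts and was at least 18.8-fold lower. Of 17 ERK targets, 4 fell (10 when adjusted over the list alone; adjusted p = 1 with an estimated correlation). Of 26 fibroblast genes, 6 rose and 6 fell with FIIN_2 (10 and 7 when adjusted over the list alone), and camera did not call the list (adjusted p = 0.507). The mitochondrial share of the FIIN_2 well was 1.41% (95% Wilson interval 1.37% to 1.45%), with 11 of 86 other compound wells higher (median 0.982%). Its 10 most counted genes held 6.05% of counts, the lowest share of the plate's compound wells (median of the others 11.5%). Of 7 interferon genes, 3 rose with either compound (3 and 4 when adjusted over the list alone; adjusted p = 0.27 and 0.12 with an estimated correlation).

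Trametinib, a MEK inhibitor on plate 1, raised epithelial genes. Upk3b (chromosome 5, 136038496 to 136046487) rose by 8.03 ± 0.42, Upk1b by 7.26 ± 0.38, the atrial myosin light chain Myl7 by 6.77 ± 0.45, Krt7 by 6.14 ± 0.54, Saa3 by 6.05 ± 0.60, Krt19 by 4.26 ± 0.63, Krt8 by 4.22 ± 0.83 and Krt18 by 3.80 ± 0.60. Of 6 epithelial genes, 4 rose (4 when adjusted over the list alone), which held with an estimated correlation (adjusted p = 0.00016). The 3 measured adipocyte genes rose (3 when adjusted over the list alone; adjusted p = 0.0022 with an estimated correlation), among them Lpl by 5.39 ± 0.55. Hspb1 rose by 4.96 ± 0.38, Lox by 4.50 ± 0.52, Lmod1 by 4.20 ± 0.79 and Actg2 by 3.98 ± 0.64. The intermediate filament desmin (Des) rose by 3.84 ± 0.50, Cnn1 by 3.83 ± 0.54, Col1a1 by 3.83 ± 0.59 and Col3a1 by 3.74 ± 0.47. Of 18 smooth muscle genes, 9 rose and 1 fell (the same when adjusted over the list alone; adjusted p = 0.47 with an estimated correlation). Ccnd1 fell by 4.61 ± 0.62, the ratio was 0.0283 for Etv4 (95% interval 0.000717 to 0.158) and 0.0422 for Etv5 (0.00107 to 0.235), and Spred1 and Nefl had 0 counts and were at least 6.71-fold and 5.39-fold lower. Of 11 ERK targets, 8 fell (9 when adjusted over the list alone; adjusted p = 1 with an estimated correlation). The 10 most counted genes of the well held 7.05% of counts, the lowest share of the plate's compound wells (median of the others 12.9%). DESeq2's size factors shifted all folds by 0.147, which raised the share of higher genes among the called from 55.8% to 67.5% (710 higher and 342 lower).

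GDC_0623, another MEK inhibitor, and LY3009120, a RAF inhibitor, raised matrix genes. The proteoglycan gene Prelp (chromosome 1, 133910304 to 133921414) rose by 7.39 ± 0.53 with GDC_0623, Pamr1 with GDC_0623 and LY3009120 by 5.39 ± 0.71 and 5.61 ± 0.49, Col1a1 by 3.69 ± 0.61 and 2.93 ± 0.41, and Lox by 3.19 ± 0.74 and 3.12 ± 0.69. Etv5 fell with both (-2.87 ± 0.71 and -2.43 ± 0.72), as did Fosl1 with GDC_0623 (-2.98 ± 0.84) and Etv4 with LY3009120 (-3.50 ± 0.63). Nptx1 had 0 counts with GDC_0623 and was at least 10.7-fold lower, and Gch1 had 0 counts with LY3009120 and was at least 13.1-fold lower. Of the fibroblast genes, 10 rose and 1 fell with each (12 and 11 rose when adjusted over the list alone; adjusted p = 0.47 and 1 with an estimated correlation). LY3009120 also raised the amino acid response: Trib3 (chromosome 2, 152337422 to 152344032) by 4.08 ± 0.50, Chac1 by 4.02 ± 0.76, Pck2 by 2.91 ± 0.31 and Slc7a5 by 2.20 ± 0.46. Of 20 such genes, 13 rose (13 rose and 1 fell when adjusted over the list alone), and camera's adjusted p was 1.1e-17, or 4.5e-09 with an estimated correlation.

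BEZ235 and PF_04979064, inhibitors of PI3K and mTOR, both raised Krt18, Krt19 and Ddit3. BEZ235 raised Cxcl10 by 5.86 ± 0.75, Cystm1 by 4.96 ± 0.68, Krt18 by 4.16 ± 0.45, Krt19 by 3.41 ± 0.55, Ddit3 by 2.71 ± 0.32, Lyz2 by 2.61 ± 0.68 and Rragd, a lysosomal activator of mTOR, by 3.71 ± 0.61, and lowered Thy1 (-3.19 ± 0.67). Of 5 epithelial genes, 3 rose (3 when adjusted over the list alone; adjusted p = 0.030 with an estimated correlation), and of 22 autophagy and lysosome genes, 10 rose (10 rose and 1 fell when adjusted over the list alone; adjusted p = 0.73 with an estimated correlation). The mitochondrial share of the BEZ235 well was 1.42% (95% Wilson interval 1.38% to 1.46%), with 4 of 40 other compound wells of the plate higher (median 1.08%). PF_04979064 raised the transcription factor Egr4 by 5.68 ± 0.72, cardiac actin Actc1 by 5.20 ± 0.63, Krt19 by 3.43 ± 0.96, Krt18 by 3.23 ± 0.82 and Ddit3 by 2.71 ± 0.49, and lowered Col6a1 (-3.11 ± 0.82) and Thy1 (-2.97 ± 0.83). Of 5 skeletal muscle genes, which include Actc1, 1 rose (4 when adjusted over the list alone; adjusted p = 0.044 with an estimated correlation). Its epithelial list was not called (camera adjusted p = 0.067, and 0.872 with an estimated correlation). Its well held 161519 counts, with a mitochondrial share of 1.34% (95% Wilson interval 1.29% to 1.40%) and 8 of 89 other compound wells of the plate higher (median 0.992%). DESeq2's size factors shifted all folds of PF_04979064 by 0.138 and raised the share of higher genes from 63.2% to 76.8% (337 higher and 102 lower). MCB_613, a stimulator of steroid receptor coactivators, raised the glutathione transferases Gsta2 and Gsta4 by 3.84 ± 0.74 and 3.74 ± 0.42, Mt3 by 3.72 ± 0.59 and Krt14 by 3.48 ± 0.95, and lowered Thy1 (-3.49 ± 0.81), Col6a2 (-3.43 ± 0.70) and the sterol gene Mvd (-3.09 ± 0.64). The 10 most counted genes of this well held 7.89% of counts, with 1 of 89 other compound wells lower (median 12.9%). The ratio for Aqp1 was 0.00748 (95% interval 0.000189 to 0.0417).

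MSC2530818 and Senexin_A, inhibitors of CDK8 and its paralog CDK19, address the kinase named in the title of the study. MSC2530818 on plate 2 raised smooth muscle genes: Myh11 (chromosome 16, 14194535 to 14291372) by 6.77 ± 0.49, Actg2 (chromosome 6, 83512905 to 83536265) by 5.55 ± 0.51, Cnn1 by 4.12 ± 0.47, Lmod1 by 3.72 ± 0.83, Acta2 by 3.68 ± 0.65, Fhl1 by 3.63 ± 0.47 and Myl9 by 3.12 ± 0.54. Of 19 smooth muscle genes, 10 rose (14 when adjusted over the list alone), and camera's adjusted p was 1.8e-50, or 4.5e-09 with an estimated correlation. The neuropeptide gene Gal rose by 4.88 ± 0.67, and Mrc2 fell (-1.43 ± 0.36). Of 15 TGF-beta response genes, 1 rose, Timp3 by 1.89 ± 0.45 (4 when adjusted over the list alone; adjusted p = 0.034 with an estimated correlation). In all, 32 genes were called by edgeR, 31 higher and 1 lower, and 19 by DESeq2. Senexin_A on plate 3 had 0 genes called by edgeR and 0 by DESeq2, with 234 at an unadjusted p under 0.05, and a smooth muscle score of 0.0296. As a pair, the 2 inhibitors had 14 called genes, all higher (7 by DESeq2). They were led by Actg2 (4.54 ± 0.50), Cnn1 (3.21 ± 0.48), Fhl1 (2.76 ± 0.46), Acta2 (2.75 ± 0.62) and Myl9 (2.33 ± 0.46). Without MSC2530818, which decides these values, 0 genes were called, and Senexin_A alone had Actg2 at -0.18 and Acta2 at -0.58.

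**Figure D3:**
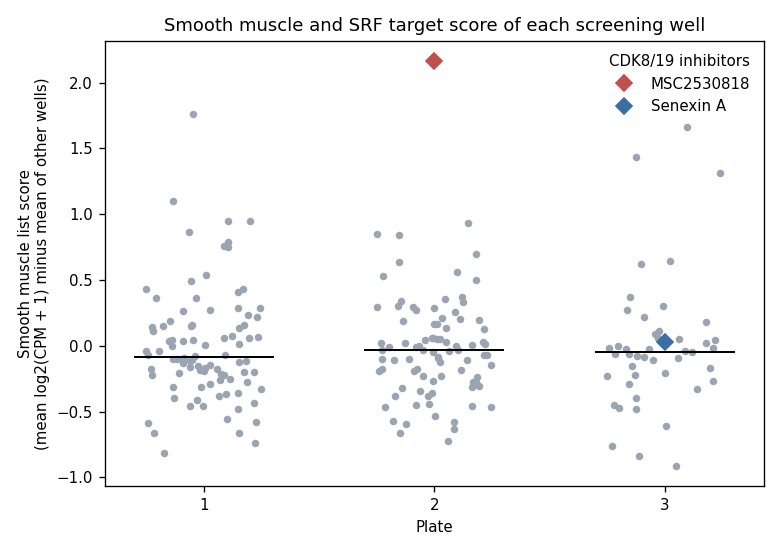
Smooth muscle score of each screening well by plate, the mean over the list of log2(CPM + 1) minus the mean of the other wells, with the plate median as a black line and MSC2530818 and Senexin_A as diamonds. MSC2530818 stood at 2.17, the highest of all wells shown, and Senexin_A at 0.0296.

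Across all 211 compounds and 26 lists, camera called 312 of 5399 pairs, 178 higher and 134 lower, and 20 of them with an estimated correlation. The bC8FAE wells had 1 call in 130. By list, the numbers of compounds called were 41 for G2/M phase, 33 for autophagy and lysosome, 31 for smooth muscle, 30 for S phase, 21 for fibroblast, 18 for cholesterol synthesis, 17 for skeletal muscle, 16 for inflammatory, 14 for ERK, 13 for mitochondrially encoded, 10 for Wnt, 9 each for p53 targets and macrophage, 8 each for epithelial, ATF4 and heat shock, 7 for YAP, 6 for interferon, 5 for adipocyte, 2 each for TGF-beta, unfolded protein response and pluripotency, 1 each for endothelial and neural, and 0 for extraembryonic endoderm and FOXO targets (fry called 5 and 7 for these). BAY1217389, an inhibitor of the mitotic kinase TTK, raised Cxcl10 by 4.74 ± 0.63 and the interferon list (1 of 3 genes, 2 when adjusted over the list alone; adjusted p = 7.5e-05 with an estimated correlation). NMS_1286937, a PLK1 inhibitor, had the highest inflammatory score, 1.62 (0 of 13 genes called, also 0 when adjusted over the list alone; adjusted p = 0.015 with an estimated correlation).

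Target classes were compared with the other compounds of their plates to ask which effects inhibitors of 1 kinase family share. The 3 MEK inhibitors on plate 1 had 1445 called genes, 772 higher and 673 lower. With DESeq2's size factors 873 were higher and 530 lower. Prelp rose by 7.34 ± 0.29, the microfibril gene Mfap5 by 5.91 ± 0.32, Saa3 by 4.83 ± 0.53, Lpl by 4.56 ± 0.41, Hspb1 (chromosome 5, 135887919 to 135889563) by 4.01 ± 0.27, Lox by 3.96 ± 0.33, Col1a1 by 3.64 ± 0.30, Actg2 by 3.38 ± 0.46, Tubb3 by 3.18 ± 0.25, Col3a1 by 3.17 ± 0.28, Krt19 by 3.09 ± 0.54 and Dcn by 2.63 ± 0.34. Etv4 (-3.07 ± 0.44), Fosl1 (-3.03 ± 0.55), the junction gene Esam (-3.76 ± 0.68), Spp1 (-5.07 ± 0.95) and Id1 (-1.39 ± 0.19) fell, and Egr1 and Frzb had 0 counts and were at least 3.26-fold and 6.27-fold lower. Some of these values rested on Trametinib. Without it, Krt19 was at -0.02 and Saa3 at 0.47, neither of them called, and Hspb1 was at 2.47 and Lpl at 2.94. Egr1 was not called without Trametinib or without GDC_0623. The ERK score was lower by 2.52 than in the other compounds of the plate in 3 of 3 wells (permutation test, adjusted p = 0.0061), and 9 of 11 ERK targets fell (10 when adjusted over the list alone; camera adjusted p = 0.16 with an estimated correlation). The S phase score was lower by 1.32 in 3 of 3 wells (permutation test, adjusted p = 0.021), with 9 of 20 genes lower (10 when adjusted over the list alone; camera adjusted p = 0.73 with an estimated correlation). The endothelial score, of 3 measured genes, was lower by 1.98 in 3 of 3 wells (permutation test, adjusted p = 0.011), but camera did not call it (adjusted p = 0.52, and 0.79 with an estimated correlation). The class had 482 called genes without Trametinib and 847 without GDC_0623. With 1 compound left out, the ERK score was -2.90 to -2.03 and no longer past the threshold without GDC_0623. The S phase score was -1.62 to -0.852 and not past it in any of the 3 cases. The endothelial score was not past it without Ro_5126766 (-1.29), a well of 45416 counts (plate median 318166). With wells thinned to that total, S phase (-1.58) and endothelial (-1.89) were not, nor S phase as a median (-1.0).

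The 3 FGFR inhibitors on plate 2 had 704 called genes that were higher and 448 that were lower (765 and 395 with DESeq2's size factors). Sst (chromosome 16, 23889573 to 23890958) rose by 7.07 ± 0.39, Saa3 by 4.32 ± 0.57, C1ra by 4.31 ± 0.53, the vitamin D receptor Vdr by 3.72 ± 0.39, Col1a1 by 3.49 ± 0.25, Lox by 3.17 ± 0.48, Col3a1 by 3.15 ± 0.22 and the immunoproteasome gene Psmb8 by 2.08 ± 0.49. Dusp4 (-2.09 ± 0.57), Spp1 (-2.01 ± 0.70), Fosl1 (-1.58 ± 0.35), Etv5 (-1.39 ± 0.27) and Cdt1 (-1.16 ± 0.25) fell. These 5 were further from 0 without SU_5402, at -3.48, -5.90, -4.32, -2.92 and -2.35. Without Erdafitinib they were at -1.70, -1.45, -0.99, -0.91 and -0.83, none of them called. Without FIIN_2 all but Etv5 lost the call (-1.74, -1.45, -1.22 and -0.81 for the other 4). Psmb8 was not called without Erdafitinib (1.05), nor Saa3 without FIIN_2 (2.02). The ERK score was lower by 1.38 in 3 of 3 wells (permutation test, adjusted p = 0.021), with 9 of 13 targets lower (10 when adjusted over the list alone; camera adjusted p = 0.17 with an estimated correlation). The interferon score was higher by 1.22, in 2 of 3 wells (permutation test, adjusted p = 0.032; 2 of 3 genes rose, also when adjusted over the list alone; camera adjusted p = 0.28 with an estimated correlation). Neither score was past the threshold without Erdafitinib (ERK -1.06, interferon 1.01) or without FIIN_2 (ERK -1.17, interferon 0.817). Nor was either as a median over members (ERK -1.31, interferon 1.13) or in wells thinned to 45416 counts (ERK -0.969, interferon 0.587), and interferon was not past it over members with a mean of at least 10 CPM (0.426). The count was 149 without Erdafitinib, 323 without FIIN_2 and 2380 without SU_5402.

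The 4 mTOR and PI3K/mTOR inhibitors, on 3 plates, had 1094 called genes, 617 higher and 477 lower. Cystm1 rose by 3.39 ± 0.55, the cornified envelope gene Sprr1a by 3.23 ± 0.46, Actc1 by 3.19 ± 0.47, Krt18 by 2.58 ± 0.45, the growth arrest RNA Gas5 (chromosome 1, 161034422 to 161038539) by 2.46 ± 0.14, Ddit3 by 2.12 ± 0.25, Atf5 by 1.63 ± 0.31, Sqstm1 by 1.35 ± 0.28 and Atf4 by 0.88 ± 0.14. Wif1 (-2.16 ± 0.68), Pycr1 (-1.96 ± 0.57), which makes proline, Thy1 (-1.19 ± 0.36) and Calr (-0.91 ± 0.16) fell. Without BEZ235, Cystm1 (1.87), Krt18 (1.26), Sqstm1 (1.07), Wif1 (-2.17), Pycr1 (-1.87) and Thy1 (-0.87) were not called. Without PF_04979064, Actc1 (1.11), Wif1 (-2.02), Pycr1 (-1.81) and Thy1 (-0.91) were not called, and without CC_115, Atf4 (0.52), Wif1 (-1.71) and Pycr1 (-1.34) were not. Without PI_103, Pycr1 was at -3.16 and Thy1 at -2.20. The count was 122 without BEZ235, 264 without PF_04979064 and 727 with no filter on low counts. DESeq2's size factors shifted the folds by 0.0724 and raised the share of higher genes from 56.4% to 69.2% (766 higher and 341 lower).

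The 9 PLK inhibitors, on 2 plates, had 982 called genes, 468 higher and 514 lower, of which 61 changed at least 2-fold. The balance of directions depended on the scaling, with 507 higher and 436 lower with DESeq2's size factors. The mitotic genes Aurkb (-1.61 ± 0.35), Cenpe (-1.47 ± 0.37) and Cdk1 (-1.46 ± 0.32) fell, as did Wif1 (-1.98 ± 0.49), Fabp5 (-1.70 ± 0.48), Nkd1 (-1.04 ± 0.22) and Tyms (-0.85 ± 0.15). The G2/M score was lower by 0.949 in 8 of 9 wells (permutation test, adjusted p = 0.011), with 18 of 21 genes lower (19 when adjusted over the list alone; camera adjusted p = 0.44 with an estimated correlation). Spp1 rose by 1.41 ± 0.29, the chemokines Ccl2 and Ccl7 by 1.19 ± 0.37 and 0.97 ± 0.18, Lyz2 by 1.17 ± 0.32, the lysosomal glycoprotein gene Gpnmb by 1.08 ± 0.20 and Mdm2 by 0.81 ± 0.16. The inflammatory score was higher by 0.942 in 9 of 9 wells (permutation test, adjusted p = 0.0061), with 5 of 11 genes higher (7 when adjusted over the list alone; camera adjusted p = 0.056 with an estimated correlation). The autophagy and lysosome score was higher by 0.394 in 8 of 9 wells (permutation test, adjusted p = 0.021), with 10 of 19 genes higher (13 when adjusted over the list alone; camera adjusted p = 0.28 with an estimated correlation). As medians over members, the inflammatory score (0.467) and the autophagy score (0.302) were not past the threshold. The autophagy score was not past it with a pseudocount of 0.1 CPM (0.449) or in thinned wells (0.490) either.

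The 11 VEGFR/PDGFR inhibitors, on 3 plates, had 198 called genes, 122 higher and 76 lower. In all there were 122 with no filter on low counts and 490 with all wells of a compound kept. Nefm (-1.41 ± 0.28), Psme4 (-1.35 ± 0.25), Egr1 (-1.34 ± 0.35), the growth factor Hbegf (-1.08 ± 0.25) and Nefl (-0.86 ± 0.25) fell, and Lox and pyruvate carboxylase (Pcx) rose by 1.36 ± 0.39 and 1.22 ± 0.19. The neural score was lower by 0.502 in 11 of 11 wells (permutation test, adjusted p = 0.021), with 2 of 6 genes lower (2 when adjusted over the list alone; camera adjusted p = 0.27 with an estimated correlation). It was not past the threshold with a pseudocount of 0.1 CPM (-0.513), as a median over members (-0.490) or in thinned wells (-0.862). The 6 inhibitors of CDK1, 2, 7 and 9 had 137 called genes (89 with no filter on low counts), 11 of them lower, led by the higher Lmod1 (2.27 ± 0.49), Tagln (1.37 ± 0.32), Perp (1.09 ± 0.24) and Actn1 (0.93 ± 0.17). The RAF class had 40 called genes, 0 without LY3009120, 75 without the BRAF inhibitor and 78 without Dabrafenib. LIMK had 2, ALK and CDK4/6 had 1 each, and the other 14 classes had 0 in edgeR's test, with 111 to 565 genes at an unadjusted p under 0.05. In DESeq2's test, all of these and RAF had 0. Of 610 pairs of class and list, 9 passed the permutation test after adjustment, 8 of these also camera with the preset correlation and 0 with an estimated one.

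Wells with forms of 1 compound were compared to ask how far a compound's profile repeats. Over 9 such pairs, the mean Pearson r across genes was 0.240, against a median of 0.0136 for random pairs (resampling test, one-sided, p = 2e-05). Genes are not independent replicates. CC_115 and its hydrochloride had r = 0.541 (rank among other pairs, adjusted p = 0.022). The CFI_400945 free base and fumarate had r = 0.541 (rank among other pairs, adjusted p = 0.037), and the other 7 pairs were not past the threshold. Reference wells shared within a plate add to r: a simulation without effects gave 0.0113 to 0.0205, and separate sets of reference wells gave a mean of 0.253 for the 7 pairs on 1 plate, against 0.279 with shared ones. For CC_115 the covariance was 0.103, against 0.00304 in the simulation. The 5 pairs of analogs had a mean r of 0.109 (permutation test, p = 0.039), from -0.0981 for BMS_3 and BMS_5 to 0.303 for Centrinone and Centrinone_B.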

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

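The test of reads shared between actin genes and the tests of a mixture with reads from wells without cells were chosen only after the result was seen. In the media with 4 to 10 wells, 24 measures were checked in each of 5 groups for a single well far from the others. Of these 120 checks, 15 found one, where chance gives about 1 in 20, or 6.0. They were not spread evenly, since 9 of the 15 fell on the low wells bC8FAE 4 and MEF 3.

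In bC8FAE 4, the mitochondrial share of counts was 1.95% (95% Wilson interval 1.88% to 2.03%) and 0.876% to 1.06% in the other 4 wells. This well had 9429 genes detected against 10992 to 11555, and 7.51% of its counts in the 10 most counted genes against 11.2% to 12.6%. Its mean log2(CPM + 1) was 10.33 for the mitochondrially encoded list against 9.33 to 9.61, 5.46 for the inflammatory list against 4.50 to 4.77 and 6.72 for YAP targets against 5.61 to 5.81. In MEF 3, the mitochondrial share was 1.43% (95% Wilson interval 1.37% to 1.49%) against 0.653% to 0.771% in the other 3 wells. Its mean log2(CPM + 1) was 8.61 for the inflammatory list against 6.14 to 6.31, and 6.64 for FOXO targets against 5.81 to 5.91.

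The higher mitochondrial share of these wells was weighed as the first pattern. Adding as many reads of the kind found in wells without cells as the deepest such well held would bring bC8FAE 4 to 1.288% and MEF 3 to 1.058%, both under the lower bound of the observed share. This argues against such reads as the whole cause. A well with damaged cells would also have a low total and a high mitochondrial share, and stays open, as it was not tested. No biological explanation was tested, since the wells of a medium share their group.

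The other single wells were MEF 4 for YAP targets (mean log2(CPM + 1) of 6.32 against 5.80 to 5.86), MEF 2 for the endothelial list (4.57 against 3.37 to 3.55), bCLFAE 1 for ATF4 targets (6.23 against 6.08 to 6.09), bCLFAE 3 for FOXO targets (4.82 against 5.42 to 5.49) and the neural list (5.76 against 6.25 to 6.30), and bCSFAE 3 for the smooth muscle list (7.19 against 6.95 to 6.98). These 6 are as many as chance gives in 120 checks. The wells named nocell, used in no comparison, held 4280 counts (nocell 2) and 25308 counts (nocell 3), above the 3 counts that a count of 0 allows.

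The second pattern was the near absence of counts in 4 compound wells, with totals of 3196 for CDK_IN_2, 3528 for LY2857785, 5774 for FLLL32 and 5154 for FRAX486, where the next lowest compound well, Ro_5126766, held 45416. Over the 1000 most counted genes of the well, r with the mean of the plate's other wells was 0.5153, 0.5169, 0.5219 and 0.5057. Ordinary wells thinned to the same total had a 2.5th percentile of 0.4754, 0.4469, 0.4889 and 0.4768, and medians of 0.5172, 0.4997, 0.5315 and 0.527. These profiles are consistent with reads that come from other wells of the plate. A well whose RNA was captured poorly predicts the same values, so cell loss and failed capture stay open.

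The third pattern was the rise of smooth muscle genes in the MSC2530818 well. A well that held bCFAE in place of the screening medium would move 291 other genes that differ between these media by a median near 1.399 on the log2 scale, and their median shift was 0.01752 (other wells -0.336 to 1.255, SD 0.217). Reads shared between actin genes are argued against by the other list members, of which 7 of 16 were called, against 22 of 9409 genes outside the list (one-sided Fisher exact test, p = 1.34e-14). Depth is argued against as well, since with all wells of the plate thinned to 45416 counts the list score of the well was 2.312 and the next highest 1.301 (2.17 and 0.932 at full depth). A biological response to the compound may explain the rise, but with 1 well a wrong well name or a mixture with other cells also stays open, and neither was tested. The columns named bC8FAE_BI and bC8FAE_MSC, in no barcode list, were not analysed here.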

How the results depend on the processing

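The alternatives for the media comparisons, the bC8FAE reference on plate 3 and the separate reference wells for pairs were chosen after seeing the data, and the other alternatives before. Of 12666 values of named genes under an alternative, 11503 had the same direction and side of the threshold, 1158 the same direction but no longer past the threshold, and 5 reversed. Those 5 came from leaving out 1 compound: without Trametinib the MEK class had Btg2 at -0.23 and Krt19 at -0.0232, without Erdafitinib the FGFR class had Lmod1 at -0.37, and without MSC2530818 the CDK8/19 pair had Acta2 at -0.58 and Actg2 at -0.18. Of 162 list values of the media, 127 were on the same side of the threshold and 35 were no longer past it. Of 624 list scores of compounds, 96 moved by more than the spread, and 68 of 1607 counts of other compounds and 16 of 154 counts of other classes moved by over 1.5 times.

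Among the media, DESeq2 called 39 genes for basal against MEF, 2150 for bCFAE against basal, 2026 for bC8FAE against MEF, 606 for bC8FAE against bCFAE, 476, 809, 350 and 341 for bC6FAE[2], bC6FAE[10], bCLFAE and bCSFAE against bCFAE, and 24 for bC6FAE[10] against bC6FAE[2]. These counts, and those with DESeq2's size factors and without a filter on low counts, were within 1.5 times the reported ones. Without the 2 low wells, MEF 3 and bC8FAE 4, basal against MEF had 76 called genes (42 higher and 34 lower), bC8FAE against MEF 2203 and bC8FAE against bCFAE 932. Leaving out 1 well at a time gave 25 to 62 genes, 2029 to 2283, 1866 to 2302, 489 to 813, 368 to 476, 731 to 836, 276 to 408, 279 to 374 and 8 to 30, in the order above.

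The numbers in the well names did not pair the wells. Wells of different media with the same number had a mean r across genes of 0.0336, 0.0138, 0.00117 and 0.0513 for numbers 1 to 4, against -0.0055 for other pairs. With these numbers as a replicate block, the counts were 51, 2596, 2270, 640, 647, 990, 459, 458 and 24.

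For compounds, the calls without a filter on low counts were 181 for MCB_613 and 220 for PF_04979064, and by DESeq2 189 for GDC_0623 and 19 for MSC2530818. The cause was not tested. With the 5 bC8FAE wells as the reference on plate 3, LY3009120 had 589 called genes, THZ1_(Hydrochloride) 834 in place of 93, Brigatinib 484 in place of 48 and Rigosertib 459 in place of 28. Then 7 compounds, not 3, had at least 100 and 16, not 7, had any. The cause was not tested. A minimum count of 5, a reference without the 10 wells of the lowest totals, DESeq2's size factors and the other minimums on well totals left the counts of the 10 compounds with the most calls within 1.5 times.

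For target classes, no filter on low counts gave 89 genes for CDK1/2/7/9, 727 for mTOR and PI3K/mTOR and 122 for VEGFR/PDGFR, and all wells of a compound kept gave 490 for VEGFR/PDGFR. DESeq2 gave 0 for RAF and 7 for CDK8/19, and 0 of the 17 classes with fewer calls had any, in place of 3. The cause was not tested. Leaving out 1 compound gave 482 to 1550 genes for MEK (847 without GDC_0623), 0 to 78 for RAF (75 without the BRAF inhibitor), 122 to 1453 for mTOR and PI3K/mTOR (264 without PF_04979064), 149 to 2380 for FGFR (323 without FIIN_2) and 0 to 32 for CDK8/19.

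Of the 9 list scores of classes past the threshold, a pseudocount of 0.1 CPM took away PLK autophagy (0.449) and VEGFR/PDGFR neural (-0.513), and 10 CPM gave 17 pairs past it. Only members with a mean of at least 10 CPM took away FGFR interferon (0.426). The median over members left 3 pairs, without FGFR interferon (1.13) and ERK (-1.31), MEK S phase (-1.0), PLK inflammatory (0.467) and autophagy (0.302), and VEGFR/PDGFR neural (-0.490). Wells thinned to 45416 counts also left 3 pairs, without FGFR interferon (0.587) and ERK (-0.969), MEK S phase (-1.58) and endothelial (-1.89), PLK autophagy (0.490) and VEGFR/PDGFR neural (-0.862). The cause was not tested. Leaving out 1 compound gave 0.817 to 1.84 for FGFR interferon (1.01 without Erdafitinib), -1.90 to -1.06 for FGFR ERK (-1.17 without FIIN_2), -1.62 to -0.852 for MEK S phase (-1.48 without Ro_5126766), -2.90 to -2.03 for MEK ERK (-2.62 without GDC_0623) and -2.33 to -1.29 for MEK endothelial, where fewer wells raise the lowest p that can be reached.

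In camera with an estimated correlation, all 9 lost the call: adjusted p was 0.282 for FGFR interferon, 0.174 for FGFR ERK, 0.729 for MEK S phase, 0.159 for MEK ERK, 0.791 for MEK endothelial, 0.056 for PLK inflammatory, 0.437 for PLK G2/M, 0.282 for PLK autophagy and 0.267 for VEGFR/PDGFR neural. MEK endothelial had adjusted p = 0.523 with the preset correlation and 0.218 in fry. The pairs of compound and list called were 20 with an estimated correlation and 125 in fry, in place of 312. Over genes called in either well, r was 0.853 for the 1 pair of forms with at least 10 such genes and -0.331 for the 1 such pair of analogs. The mean r of all pairs was 0.396 for forms and 0.202 for analogs over genes with a mean of at least 50 CPM, in place of 0.240 and 0.109, and 0.244 and 0.116 with Spearman's rho, all past the threshold in the resampling test. The cause was not tested. The yield alternative equals the reported one, as there were 0 ERCC genes. Leaving out each of the 5 bC8FAE wells from the reference of plate 3 gave 1603 to 1658 called genes for LDC4297, 927 to 971 for BEZ235, 377 to 401 for LY3009120 and 0 for Senexin_A, and 3 to 4 compounds with at least 100 called genes. Rigosertib had 18 in place of 28 without bC8FAE 1 or 3. The plate differences were fitted on compound wells, so this alternative did not apply to them. Depth limits genes with few counts.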

Other observations

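The counts of other splits, the comparison of FGFR, MEK and RAF inhibitors across plates and the test of both CDK8/19 inhibitors were chosen only after the result was seen. Some inhibitors at 3 levels of 1 pathway had like profiles on separate plates. The FGFR inhibitor Erdafitinib on plate 2 had r = 0.747 across genes with the MEK inhibitor GDC_0623 and r = 0.733 with Trametinib on plate 1, and the RAF inhibitor LY3009120 on plate 3 had r = 0.670 with GDC_0623. Among 15087 pairs of wells on different plates, the median r was 0.0123, and 1 in 1000 was above 0.655. Pairs on different plates share no reference wells, but genes are not independent replicates. For all 9 wells of the 3 classes, 23 pairs on different plates had a mean r of 0.193 over 7265 genes, where random wells had a median of 0.00225 (permutation test, one-sided, p = 7e-05). Of the 23 pairs, 13 were above 0 and 10 under 0. The lowest r was -0.214 for SU_5402 (with Trametinib), -0.215 for the BRAF inhibitor (with FIIN_2) and -0.153 for Dabrafenib (with LY3009120). The hypothesis that blocking FGFR, MEK or RAF moves the same genes was found and tested on these data, and 3 of the 9 wells did not follow it.

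A second hypothesis was that both CDK8/19 inhibitors raise the smooth muscle genes that the screening medium holds low. The list score of Senexin_A was 0.02959, inside the central 95% of the other wells of plate 3, which ended at 1.42, and 30 of the 45 other wells of that plate had a lower score. MSC2530818 stood at 2.17, where the central 95% of plate 2 ended at 0.824. These 2 wells argue against the hypothesis at the concentration used, with 1 well each, and the columns named bC8FAE_BI and bC8FAE_MSC were not analysed here. A lower potency of Senexin_A may explain the difference and was not tested.

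Next, the wells of a comparison were refitted alone in other splits of the same sizes. The real split called the most genes for basal against MEF (27 genes, highest other 17, 1 of 35 splits as large). So it did for bC8FAE against MEF (1495 and 982, 1 of 100) and bCFAE (521 and 5, 1 of 56). Against bCFAE it did for bC6FAE[10] (1121 and 0), bCLFAE (616 and 105) and bCSFAE (592 and 134), each 1 of 35. For bC6FAE[10] against bC6FAE[2] it did too (90 and 23, 1 of 35). Chance is unlikely for these. For bCFAE against basal (2287, highest other 0) and bC6FAE[2] against bCFAE (734 and 0) the 10 splits are too few for a share under 0.05.

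For target classes, other sets of compounds of the same size and plates were drawn. Of 100 sets, the real class called the most genes for MEK (1432, highest other 399) and FGFR (1146 and 941). So it did for mTOR and PI3K/mTOR (1096 and 327) and PLK (979 and 283). Chance is unlikely for these counts, uncorrected for 24 classes. It cannot be excluded for VEGFR/PDGFR (198 and 308, 2 of 100 sets as large) or CDK1/2/7/9 (137 and 644, 7). Nor can it, over 25 sets, for RAF (40 and 213, 3 sets), ALK (1 and 48, 6), LIMK (2 and 701, 7) and CDK4/6 (1 and 701, 9). The other 14 classes called 0 genes, which all 25 sets reached (highest others 58 to 1905). Sets far above the real count point to a structure of the wells, as a few compounds per plate had many calls. This test cannot tell strong wells from a shared effect.

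The plates differed in many genes by small amounts. Plate 2 had 1899 called genes against plate 1 (4 of them at least 2-fold), plate 3 had 2380 against plate 1 (107) and 2496 against plate 2 (88). In 100 splits of the same wells, the real one alone called as many (1898, 2365 and 2486 in these refits). The highest others were 8, 14 and 47, so chance is unlikely. Plates held mostly different compounds, so plate and compound were not separated, and classes had a plate term.

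The total count of a well and its mitochondrial share were related within each plate, with Spearman's rho of -0.571 on plate 1 (90 wells), -0.699 on plate 2 (87 wells) and -0.609 on plate 3 (41 wells; permutation test, p = 1e-05, 1e-05 and 5e-05, of which 1e-05 is the smallest it can give). Pearson's r was -0.540, -0.776 and -0.452 (permutation test, p = 1e-05, 1e-05 and 0.00325; adjusted over the 3 plates 1.5e-05, 1.5e-05 and 0.00325). Without the 2 wells farthest in total it was -0.710, -0.789 and -0.391. No target class of at least 3 compounds differed in total count after adjustment. The lowest p was that of MEK (median ratio 0.784, lower in 2 of 3 wells; permutation test, p = 0.0501, adjusted p = 0.702).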
